A study of Mus musculus with 4 samples.

How the data were processed

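Muscle progenitor cells of C57Bl/6 mice were profiled on a whole-transcript Affymetrix microarray. The series held 4 arrays, with 2 from aged mice (2 years) and 2 from young mice (5 weeks). Per the labels' protocols, muscle was digested with collagenase, cells stained for CD29 (integrin beta 1) and ITGA7 (integrin alpha 7) were collected by flow cytometry when positive for both, and RNA was extracted with Trizol and treated with DNase. Labelled single-stranded cDNA was made from 1 ng of RNA per array, also per the labels' protocols. The sex of the animals, the number of animals per array and the scan dates are not given in the sources used here.

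The authors deposited 1 table of log2 probe set levels with 28846 entries and 4 columns, and every column was matched to an array. Per the submitters' processing notes, the values were made with RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, and with the Transcriptome Analysis Console; their versions are not given. The deposited log2 values ran from 2.08 to 19.4, above what a plain scan usually allows. A stretched variant of RMA is therefore possible but not stated, so differences are given in the log2 units of the table and not as folds. The median level of the tested probe sets was 6.80 and 6.74 in the aged and 6.71 and 6.76 in the young arrays. The number of arrays limits the precision.

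Probe sets were named from the platform annotation. Exactly 1 gene symbol was given for 19572 probe sets, covering 19505 genes, and no probe set was paired with several genes. Symbols were read against a RefSeq gene table of the assembly GRCm38.p6, in which all 19572 gene identifiers were found. No symbol was given for 2634 transcript clusters, and 6640 entries were array controls; these were left out of the gene tests. The genome build of the array was not given, so no coordinates are printed. Where a gene had several probe sets (55 genes, of which 15 had probe sets of opposite sign), the one with the highest mean over the 4 arrays was used for lists and named genes.

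Aged and young arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated two-sided test, group as the only term, 4 arrays). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. A looser count took an unadjusted p under 0.05 and a difference of at least 1 log2 unit. Errors of differences are standard errors of this fit, and errors of group means are SDs over 2 arrays. No filter on low levels was used.

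Before the data were examined, 48 gene lists holding 894 genes were written down for muscle stem cell identity and differentiation, the cell cycle, senescence, stress, immune and growth pathways, matrix, metabolism and the other cell types that such a sort could hold. Of these genes, 811 were found, 3 of them through an older symbol. Lists with at least 5 measured members (46 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera tests on the residual degrees of freedom of the fit, here 2, so small p-values are hard to reach. Fry tests whether a list moves one way on balance and does not compare it with other genes. For each list the members were also counted with p-values adjusted over the list alone.

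The rule for named genes was fixed at the same time. It took the 12 largest differences in each direction among genes past the adjusted threshold with non-overlapping groups, leaving out predicted genes and large families, and filled the places with genes at an unadjusted p under 0.05 and at least 1 log2 unit where too few passed. No gene passed, so every gene of this part was chosen by the second condition. The rule also took up to 4 members with the smallest p from each list described, and 10 genes of prior interest, of which 9 were measured; H19 was not analysed here.

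Alternatives fixed in advance were a second quantile normalization, median centring, a filter on dim probe sets, a variance prior with a trend, a robust prior, a required difference of 1 log2 unit, the replicate block, leaving out each array in turn, every entry of the table, camera on ranks and the average of a gene's probe sets. After the data were seen, 2 were added: the exon against intron separation of each array as a covariate, and lists without members shared with other lists. For the patterns weighed in the closing section, 95% intervals between arrays were taken from linear models of each array's mean over the genes, with or without this covariate, also after the data were seen. The exon against intron separation is the area under the curve with which exon control probe sets stand above intron control probe sets on an array. As a covariate it leaves 1 residual degree of freedom. Members that no longer pass with it are therefore no sign that array quality explains a shift.

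The gene test was checked on simulated data of 2 arrays against 2 for the 19572 probe sets. Of 50 probe sets shifted by each size, the adjusted threshold called 1 at 1 log2 unit, 2 at 2 units, 45 at 4 units and 49 at 6 units, with 4 false calls in all. The looser count took 564 unchanged probe sets in the simulation. The list test called the 1 list that was shifted and no other of the 46 lists in a simulation with independent genes.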

Results

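Gene expression was measured in muscle progenitor cells sorted from aged (2 years) and young (5 weeks) C57Bl/6 mice, with 2 arrays per age. The cells were positive for CD29 and ITGA7, a pair of integrins used to enrich satellite cells, the resident stem cells of skeletal muscle. The comparison asked how the expression profile of these cells differed between the ages. Levels are the deposited log2 values of 19572 probe sets with a gene symbol, and differences are aged minus young. The labels do not say whether the arrays of an age came from separate animals, so all p-values measure only the spread between these samples.

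The 4 arrays were similar in level and differed moderately in profile. Across genes, which are not independent replicates, Pearson's r was 0.978 between the aged arrays and 0.975 between the young arrays. It was 0.965 to 0.975 between arrays of different age, so that aged replicate 2 and young replicate 2 were as similar as the young arrays. The first principal component held 44.9% of the variance and placed the aged arrays at -49.0 and -26.4 and the young arrays at 58.5 and 17.0. The separation of exon from intron control probe sets, a sign of RNA and labelling quality, was 0.792 and 0.819 in the aged and 0.849 and 0.823 in the young arrays, and so moved with age.

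The genes of the sorted proteins were read at high levels in every array. Itga7, the integrin alpha 7 gene, averaged 14.81 ± 0.34 (SD, n = 2) in aged and 14.96 ± 0.23 (SD, n = 2) in young arrays, a difference of -0.14 ± 0.33 (SE). Itgb1, encoding CD29, differed by -0.64 ± 0.37 (SE), which was -0.26 without young replicate 1 and -1.01 without young replicate 2. The satellite cell transcription factor Pax7 differed by 0.12 ± 0.51 (SE), with array levels of 9.99 and 11.04 in aged and 10.91 and 9.89 in young cells. The limma adjusted p was 0.957, 0.777 and 0.982 for these genes. The sign for Itga7 turned without aged replicate 1 (0.10), without young replicate 1 (0.02) and with the exon against intron separation as a covariate (0.33), and that for Pax7 turned without aged replicate 2 (-0.41) and without young replicate 2 (-0.40). Some markers of other cells were read at high levels too. The median level was 12.29 for fibroblast and 12.20 for pericyte and smooth muscle genes, against 11.31 for satellite cell genes. It was 7.21 for endothelial genes, and lower for the immune lists given below. The sorted samples may therefore hold other cells, and a shift cannot be assigned to muscle progenitors alone. Among Y-linked transcripts, Eif2s3y was read at 4.81 and 4.89 in aged and 5.38 and 4.92 in young arrays. All 4 of these Eif2s3y readings lay below the median of the intron controls of their array. Kdm5d was read at 7.82 and 7.86 in aged and 6.95 and 8.31 in young arrays. Uty was read at 9.79 and 10.47 in aged and 12.06 and 10.39 in young arrays. None of these Y-linked genes passed the limma test (adjusted p of 0.892, 0.959 and 0.765).

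Elane, Mpo, Jchain and Ngp had the largest positive differences between aged and young cells among the named genes, and Col26a1, Pmch and Col1a1 the largest negative ones. No gene passed the adjusted threshold in limma, however, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 1438 probe sets (7.35%), where chance alone gives 978.6. Of these, 1003 differed by at least 1 log2 unit, 442 higher and 561 lower in aged cells; with the exon against intron separation as a covariate 494 were higher and 469 lower. Both aged arrays lay on the same side of both young arrays for 36.6% of probe sets, against 33.3% by chance. Without young replicate 2 the count of 1003 was 1994, and 1 gene, Kit, passed (6.78, adjusted p of 0.0400 in limma).

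The 12 genes with the largest positive differences included 6 known from granulocytes and their precursors (Elane, Mpo, Ngp, Ctsg, Camp and Ms4a3), a grouping made after the values were seen. Mpo, encoding myeloperoxidase, averaged 15.28 ± 1.18 (SD, n = 2) in aged and 8.55 ± 0.87 (SD, n = 2) in young arrays, a difference of 6.72 ± 0.67 (SE; limma adjusted p of 0.343). Elane, encoding neutrophil elastase, differed by 6.77 ± 0.84 (SE), and Ctsg, encoding cathepsin G, by 4.75 ± 0.81. Ngp and Camp, which encode neutrophil granule proteins, differed by 5.96 ± 1.04 and 4.64 ± 1.64, and Ms4a3, a gene of granulocyte and monocyte progenitors, by 3.93 ± 0.78. Jchain, the joining chain of secreted antibodies made by plasma cells, differed by 6.24 ± 0.91. Lcp1, a leukocyte actin-bundling protein, averaged 12.57 ± 0.36 (SD, n = 2) against 8.63 ± 0.52 (SD, n = 2), and Cd69, a lymphocyte activation antigen, differed by 4.03 ± 0.71. The receptor gene Kit, known from mast cells and blood progenitors, was read at 10.87 and 11.42 in aged cells but at 4.37 and 8.68 in young cells. The myosin light chain genes Myl3 and Myl2 differed by 4.40 ± 1.74 and 4.16 ± 1.31. Their levels came mainly from aged replicate 1, with Myl3 at 15.35 there and 9.48 in aged replicate 2 against 7.94 and 8.10 in young cells. Of these 12 genes, Jchain, Ctsg, Camp, Cd69 and Ms4a3 were read below the median of the intron controls in both young arrays, and Ngp, Kit and Myl2 in 1 of them. Those young readings may be background, so the sizes of these differences are uncertain. The difference for Camp was 7.33 without aged replicate 1 and 1.95 without aged replicate 2. The limma adjusted p of these 12 genes was 0.343 to 0.675. In the same comparison the exon against intron separation was 0.792 and 0.819 in aged and 0.849 and 0.823 in young arrays.

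**Figure D1:**
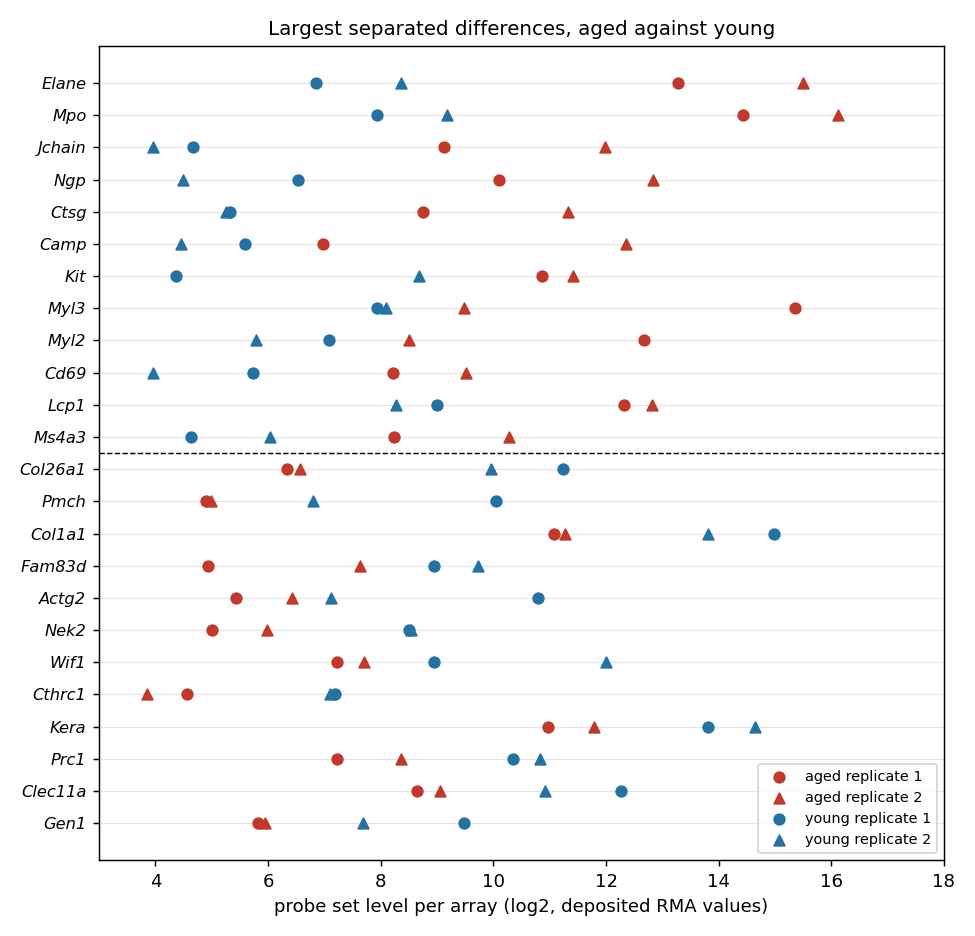
Level of each named gene on each array, in the deposited log2 units (x axis), for the 12 genes with the largest positive differences (above the dashed line) and the 12 with the largest negative differences (below it). Each point is 1 array, red for aged and blue for young, with circles for replicate 1 and triangles for replicate 2; Mpo lies at 14.44 and 16.11 in aged and at 7.94 and 9.17 in young arrays, and Col1a1 at 11.09 and 11.27 in aged and at 14.99 and 13.82 in young arrays.

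The 12 genes with the largest negative differences included 4 of the extracellular matrix (Col26a1, Col1a1, Cthrc1 and Kera) and 3 of mitosis (Nek2, Prc1 and Fam83d), again grouped after the values were seen. Col1a1, encoding the alpha 1 chain of type I collagen, averaged 11.18 ± 0.13 (SD, n = 2) in aged and 14.40 ± 0.83 (SD, n = 2) in young arrays, a difference of -3.22 ± 0.45 (SE; limma adjusted p of 0.386). Col26a1, another collagen gene, differed by -4.14 ± 0.47, and Cthrc1, a secreted protein with a collagen-like repeat, by -2.93 ± 0.35. Kera, encoding keratocan, a proteoglycan of cornea and tendon, differed by -2.85 ± 0.44, and Clec11a, a secreted growth factor of bone, by -2.74 ± 0.50. Nek2 and Prc1, which act at the centrosome and in cytokinesis, differed by -3.03 ± 0.40 and -2.80 ± 0.46, and the spindle gene Fam83d by -3.06 ± 0.87. Gen1, encoding a DNA junction resolvase, differed by -2.69 ± 0.60. Wif1, a secreted Wnt inhibitor, was read at 7.22 and 7.71 in aged and 8.95 and 11.99 in young cells. The smooth muscle actin gene Actg2 was read at 5.43 and 6.42 in aged and 10.79 and 7.12 in young cells. Pmch, the precursor of melanin-concentrating hormone, was read at 4.89 and 4.99 in aged and 10.04 and 6.80 in young cells. Of these 12 genes, Col26a1, Pmch, Actg2, Nek2, Cthrc1 and Gen1 were read below the median of the intron controls in both aged arrays, and Fam83d in 1 of them, so the sizes of these differences are uncertain too. The difference for Fam83d was -1.71 without aged replicate 1. The limma adjusted p of these 12 genes was 0.386 to 0.654, beside the same difference in exon against intron separation.

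Among the 46 gene lists tested, camera called 19, with 9 higher and 10 lower in aged cells. The higher lists held immune cell markers, interferon and antigen presentation genes and genes of mature muscle fibres, and the lower lists held mitosis, matrix, tendon, fibroblast and imprinted growth genes. No list kept its call with an estimated correlation (smallest adjusted p = 0.530, 1 list at an unadjusted p under 0.05) or by fry (smallest adjusted p of 0.241, 4 lists at an unadjusted p under 0.05). Camera with an estimated correlation rests on 2 residual degrees of freedom here. Few lists could pass it after adjustment, so the loss of calls with it says little. Without young replicate 2 the count was 12. No member of any list passed when adjusted over all genes in limma, so the counts below are of members at an unadjusted p under 0.05 and of members passing when adjusted over the list alone.

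**Figure D2:**
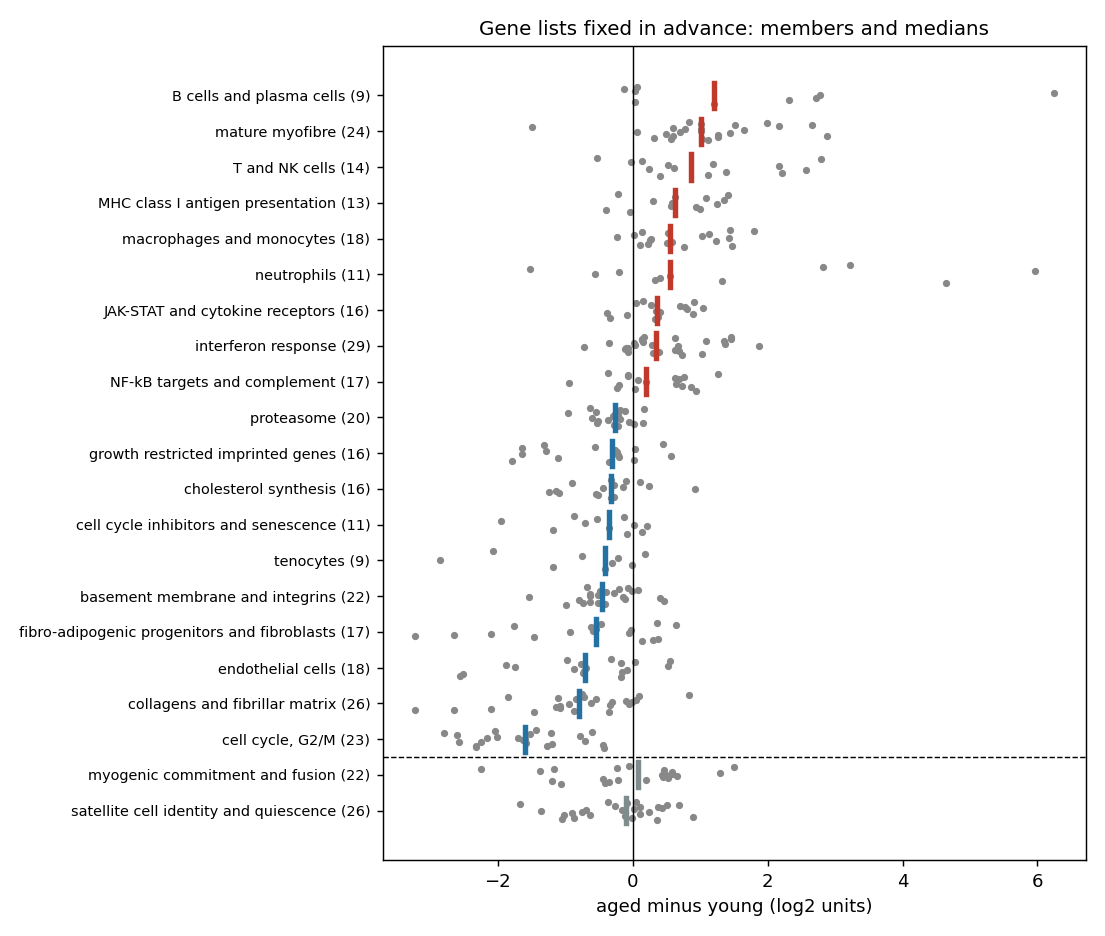
Difference between aged and young cells in log2 units (x axis) for each measured member (grey points) of the 19 lists called by camera and of the myogenic commitment and satellite cell lists, which were not called (below the dashed line). Vertical bars mark list medians, red for lists higher, blue for lists lower and grey for lists not called, and the number of measured members stands in parentheses; the G2/M list has the lowest median (-1.59) and the B cell and plasma cell list the highest (1.21).

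Genes of the G2 and M phases of the cell cycle shifted lower in aged cells. All 23 measured members had negative differences, with a median of -1.59, and 16 were at an unadjusted p under 0.05. Mki67, the proliferation marker gene, differed by -2.60 ± 0.48 (SE), with 10.87 and 11.81 in aged and 13.48 and 14.39 in young arrays. The spindle checkpoint kinase gene Bub1 differed by -2.32 ± 0.33, Prc1 by -2.80 ± 0.46 and the kinetochore motor gene Cenpe by -1.62 ± 0.31. The camera adjusted p was 4.31e-18 at the preset correlation, and adjusted p = 0.530 with an estimated correlation. None passed in limma over all genes and 16 passed adjusted over the list alone; without aged replicate 1 this was 2, and with the exon against intron separation as a covariate it was 0, while the list's median was then -1.37. The covariate left 1 residual degree of freedom, so the loss of passing members with it does not point to array quality. The separation was 0.792 and 0.819 in aged and 0.849 and 0.823 in young arrays, and macrophage markers had a median of 0.55 in the same comparison.

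Genes of the earlier G1/S phase and of DNA replication were not called (19 measured, median -0.10, camera adjusted p of 0.0853). E2f1, a transcription factor that drives entry into S phase, differed by -1.49 ± 0.33 (SE) and was the 1 member at an unadjusted p under 0.05. None passed adjusted over the list alone. This list was called lower without aged replicate 2 (median -0.45, adjusted p of 0.00680, 2 members at an unadjusted p under 0.05) and without young replicate 1 (median -0.43, adjusted p of 0.00227, 4 such members), and its median was 0.08 without aged replicate 1.

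Genes of collagens and the fibrillar matrix shifted lower in aged cells. Of 26 measured members, 23 had negative differences, the median was -0.79, 11 were lower at an unadjusted p under 0.05 and 1, Thbs2, was higher (0.84; named after its value was seen). Col1a1 differed by -3.22 ± 0.45 (SE), Col1a2 by -2.65 ± 0.46, Col3a1 by -2.10 ± 0.49 and Postn, encoding the matricellular protein periostin, by -1.85 ± 0.36. The camera adjusted p was 9.62e-09, and adjusted p = 0.530 with an estimated correlation. Over all genes 0 members passed in limma and 5 passed adjusted over the list alone. That count of 5 was 0 without aged replicate 1, 0 without aged replicate 2, 2 without young replicate 1, 4 without young replicate 2 and 0 with the exon against intron separation as a covariate, whose median was -0.71. The separation was lower in both aged arrays (0.792 and 0.819) than in both young arrays (0.849 and 0.823).

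Markers of tendon cells and of fibro-adipogenic progenitors, the fibroblast-like cells of muscle, shifted lower as well. The tendon list had 9 measured members, a median of -0.41 and 3 members lower at an unadjusted p under 0.05, all of which passed adjusted over the list alone. These were Tnmd, encoding the tendon protein tenomodulin (-2.06 ± 0.28, SE), Kera (-2.85 ± 0.44) and Cilp2 (-1.18 ± 0.31). Its camera adjusted p was 0.00120, and adjusted p = 0.530 with an estimated correlation. The tendon median was -0.25 without aged replicate 2 and -0.89 without young replicate 1, and the call was lost without young replicate 2 (adjusted p of 0.132), when 2 members passed over the list alone. The fibroblast list had 17 measured members, a median of -0.54 and 4 members lower at an unadjusted p under 0.05, namely Col1a1, Col1a2, Col3a1 and Pdgfrl (-1.75 ± 0.37); these 4 passed adjusted over the list alone. Its camera adjusted p was 0.00265, and adjusted p = 0.530 with an estimated correlation. The fibroblast median was -0.83 without young replicate 1 and 0.07 without young replicate 2, when the call was lost (adjusted p of 0.235), and the call was also lost when members shared with other lists, the collagens among them, were left out (median -0.25). At an unadjusted p under 0.05 there were 7 fibroblast markers without young replicate 1. The passing members of the fibroblast list numbered 2 without aged replicate 1, 2 without aged replicate 2 and 7 without young replicate 1. With the exon against intron separation (0.792 and 0.819 in aged, 0.849 and 0.823 in young arrays) as a covariate the medians were -1.04 for tendon and -0.96 for fibroblast markers, and 0 members of either list passed over the list alone.

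Genes of the basement membrane and its integrins shifted lower by a smaller amount. Of 22 measured members, 19 had negative differences, the median was -0.45 and 3 were at an unadjusted p under 0.05: Itga6, an integrin chain that binds laminin (-1.54 ± 0.36, SE), Agrn, encoding agrin (-0.98 ± 0.34), and Hspg2, encoding perlecan (-0.79 ± 0.31). None passed adjusted over the list alone. The camera adjusted p was 0.00235, and adjusted p = 0.530 with an estimated correlation. The call was lost without young replicate 1 (median -0.34), when members at an unadjusted p under 0.05 pointed both ways. It was also lost in camera with the exon against intron separation, which differed with age, as a covariate (median -0.33, adjusted p of 0.110).

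Markers of several immune cell types shifted higher in aged cells. The macrophage and monocyte list had 18 measured members, 17 of them positive, with a median of 0.55 and 5 at an unadjusted p under 0.05. Ptprc, the pan-leukocyte CD45 gene, differed by 1.79 ± 0.46 (SE), Aif1 by 1.48 ± 0.33, the lysosomal protease gene Ctss by 1.43 ± 0.29 and the endotoxin receptor gene Cd14 by 1.23 ± 0.29. The T and NK cell list had 14 measured members, a median of 0.87 and 6 members at an unadjusted p under 0.05, with the T cell receptor complex gene Cd3g at 2.57 ± 0.65 and the granule gene Nkg7 at 2.79 ± 0.98. The B and plasma cell list had 9 measured members, a median of 1.21 and 5 members at an unadjusted p under 0.05, with Jchain at 6.24 ± 0.91 and the class II antigen presentation gene H2-Aa at 2.32 ± 0.72. The neutrophil list had 11 measured members, a median of 0.55 and 4 members at an unadjusted p under 0.05, with Ngp at 5.96 ± 1.04 and S100a9, encoding a calprotectin subunit, at 3.22 ± 0.84. Camera adjusted p-values were 5.08e-05, 9.57e-05, 0.000778 and 0.00554 in this order. With an estimated correlation the macrophage, T cell and B cell lists each had adjusted p = 0.530 and the neutrophil list had adjusted p = 0.688. The median level was 5.53 for macrophage, 6.11 for T and NK cell, 6.91 for B cell and 5.89 for neutrophil genes. Intron control medians were 6.76 and 6.68 in aged and 6.25 and 6.62 in young arrays, and these controls had a median difference of 0.23. Many of these marker readings may therefore be background, which itself stood higher in aged arrays.

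Adjusted over the list alone, 4 macrophage, 0 T and NK cell, 4 B cell and 3 neutrophil markers passed, and none passed over all genes in limma. The macrophage count was 0 with any 1 array left out, and the macrophage median was 0.29 without aged replicate 1 and 1.23 after the dim filter. For T and NK cells 6 passed without aged replicate 1, the median was 0.47 without aged replicate 2, and the call was lost when dim probe sets were filtered out (median 0.25, adjusted p of 0.151). The B cell count was 1 without aged replicate 1, 1 without aged replicate 2 and 1 without young replicate 2, and the B cell median was 2.72 after the dim filter. The neutrophil median was 0.96 without aged replicate 2, when 0 passed, and 1.21 without young replicate 1; without young replicate 2 it was 0.20 and the call was lost (adjusted p of 0.475). It was 3.22 after the dim filter and 1.33 without shared members. Since the dim filter can keep genes that are high in the aged arrays alone, the larger medians after it are no support for these shifts. The counts at an unadjusted p under 0.05 were each 2 without aged replicate 2 for B cells and neutrophils. Among single genes, H2-Aa differed by 1.20 and S100a9 by 2.04 without young replicate 2. Without aged replicate 2 Nkg7 differed by 1.20 and Cd3g by 1.70, and without aged replicate 1 Nkg7 differed by 4.38. With the exon against intron separation (0.792 and 0.819 in aged, 0.849 and 0.823 in young arrays) as a covariate the medians were 0.54 for macrophages, 1.25 for T and NK cells, 1.38 for B cells and 1.39 for neutrophils.

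Interferon response and antigen presentation genes shifted higher in aged cells. The interferon list had 29 measured members, 23 of them positive, a median of 0.34 and 5 members at an unadjusted p under 0.05. Irgm1, an interferon-induced GTPase gene, was read at 10.17 and 10.25 in aged and 8.33 and 8.34 in young arrays (1.87 ± 0.28, SE), and the antiviral gene Mx2 and the ISG15 protease gene Usp18 differed by 1.37 ± 0.29 and 1.46 ± 0.32. The class I antigen presentation list had 13 measured members, 10 of them positive, a median of 0.63 and 4 members at an unadjusted p under 0.05. Tap2, a peptide transporter gene, differed by 1.41 ± 0.37, the immunoproteasome gene Psmb8 by 1.35 ± 0.34 and H2-Q4 by 1.25 ± 0.33. Camera adjusted p-values were 9.09e-05 and 0.000249, and both lists had adjusted p = 0.530 with an estimated correlation. None passed in limma over all genes, and 3 interferon and 3 antigen presentation genes passed adjusted over the list alone.

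Over the list alone 0 interferon genes passed without aged replicate 1, aged replicate 2 or young replicate 1, and 2 passed without young replicate 2, Irgm1 and Stat2, of which Stat2 was not among the 3. For antigen presentation 4 passed without aged replicate 1, namely Psmb8, H2-Q4, Psmb9 and H2-D1 but not Tap2 (0.103), and 0 with any other array left out; Stat2, Psmb9 and H2-D1 were named after their values were seen. The interferon median was 0.54 without aged replicate 1 and 0.65 after the dim filter, and the antigen presentation median was 1.04 without aged replicate 1 and 0.39 without aged replicate 2, when 2 of its members were at an unadjusted p under 0.05. With the exon against intron separation (0.792 and 0.819 in aged, 0.849 and 0.823 in young arrays) as a covariate the medians were 0.50 and 1.04, and 0 members of either list passed over the list alone. The pan-leukocyte gene Ptprc, which marks cells that also express these genes, was 1.79 higher in the same comparison.

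Cytokine receptor and NF-kB target genes shifted higher by small amounts. In the same comparison the pan-leukocyte gene Ptprc was 1.79 higher and macrophage markers had a median of 0.55. The JAK-STAT list had 16 measured members, a median of 0.36 and 3 at an unadjusted p under 0.05: the oncostatin M receptor gene Osmr (1.04 ± 0.33, SE), Stat3 (0.91 ± 0.32) and the leukaemia inhibitory factor receptor gene Lifr (0.81 ± 0.30). The NF-kB and complement list had 17 measured members, a median of 0.20 and 3 at an unadjusted p under 0.05: the complement gene C4b (0.87 ± 0.32), Nfkbiz (0.77 ± 0.31) and Tnfaip3 (1.27 ± 0.51). None of either list passed adjusted over the list alone. Camera adjusted p-values were 0.00682 and 0.0426, and both lists had adjusted p = 0.530 with an estimated correlation. The JAK-STAT call was lost without young replicate 1 (adjusted p of 0.0597), its count of 3 at the unadjusted threshold was 0 without aged replicate 2 and 1 without young replicate 1, and 1 passed over the list alone without young replicate 2, and with the exon against intron separation as a covariate the adjusted p was 0.141. The NF-kB call was lost without aged replicate 2 (median 0.26, adjusted p of 0.166), without young replicate 1 (0.41, adjusted p of 0.0751), without young replicate 2 (0.33, adjusted p of 0.178), with that covariate (0.48, adjusted p of 0.122), on ranks (adjusted p of 0.0736) and without shared members (adjusted p of 0.0662), and its median was 0.56 without aged replicate 1. The NF-kB median was 0.41 after the dim filter and 0.63 without shared members. Fewer of its members were at the unadjusted threshold without aged replicate 2 and without young replicate 2, in the latter pointing both ways. Tnfaip3 differed by 0.75 and 0.76 in these 2 settings.

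**Figure D3:**
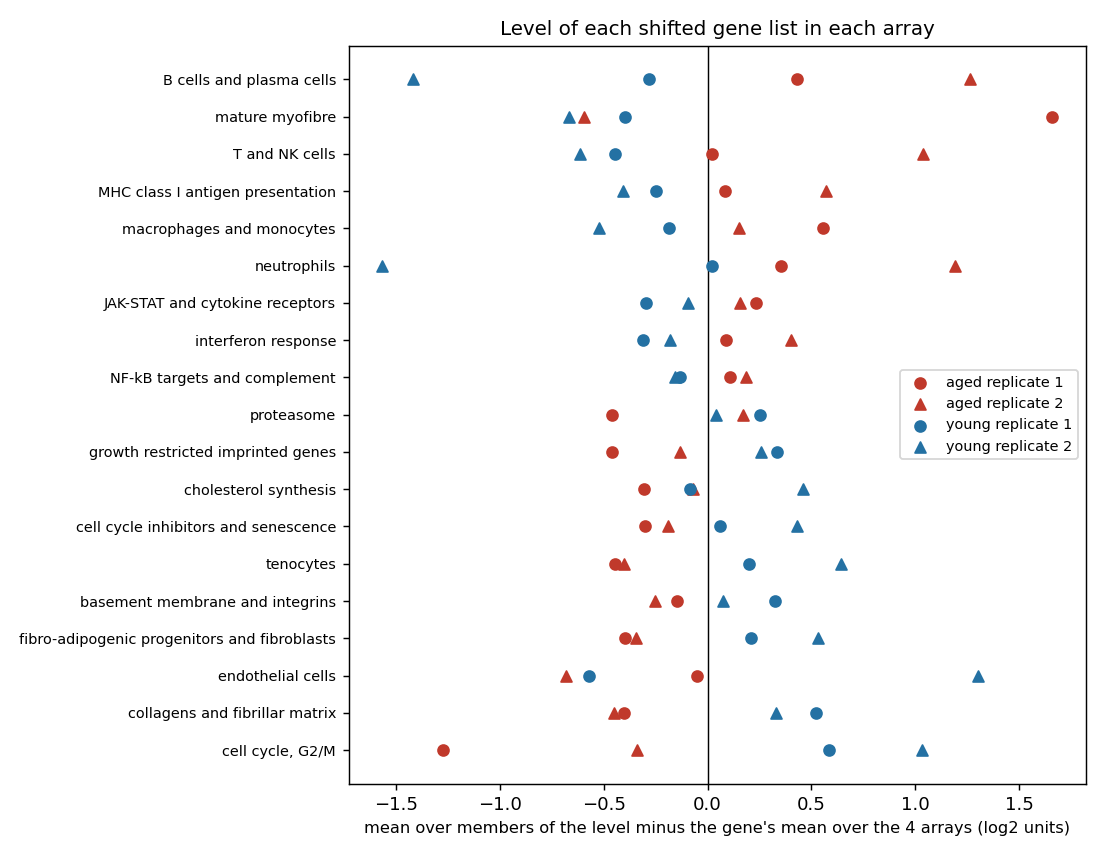
Mean over the members of each called list of the level on an array minus the gene's mean over the 4 arrays, in log2 units (x axis), 1 point per array, red for aged and blue for young, with circles for replicate 1 and triangles for replicate 2. Mature myofibre genes stand high in aged replicate 1 alone (1.66) and endothelial genes in young replicate 2 alone (1.30), while both aged arrays lie below both young arrays for the G2/M list.

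Genes of satellite cell identity were not called as a list, whereas the genes of the myogenic regulators Myog and Myod1 had negative differences. The satellite cell list had 26 measured members with a median of -0.10 (camera adjusted p of 0.204), and 2 were lower at an unadjusted p under 0.05, Megf10 (-1.36 ± 0.45, SE) and Sox8 (-1.67 ± 0.64). It was called lower without young replicate 2 (median -0.43, adjusted p of 0.00997), its median was -0.27 without aged replicate 2 and 0.06 without young replicate 1, and it was 0.06 with the exon against intron separation as a covariate. Its count of 2 was 1 without aged replicate 1 and 6 without young replicate 2, and without young replicate 1 there were 3 higher and 2 lower. Megf10 differed by -0.87 without aged replicate 1, and Sox8 by -2.64 without young replicate 1 and -0.71 without young replicate 2. Myog, encoding the differentiation factor myogenin, was read at 11.80 and 13.87 in aged and 14.38 and 15.80 in young cells, a difference of -2.25 ± 0.79 (SE). Myod1 differed by -1.16 ± 0.43, and the acetylcholine receptor gene Chrna1 by -1.20 ± 0.39, while the embryonic myosin gene Myh3 differed by 1.30 ± 0.45. Without aged replicate 1 these differences were -1.22 for Myog, -0.62 for Myod1, -0.75 for Chrna1 and 0.80 for Myh3. The limma adjusted p over all genes was 0.609 for Myog and 0.647 for Myod1. The myogenic commitment list was not called (22 measured, adjusted p of 0.878): its median was 0.07 while its mean was -0.07 and its test pointed lower, with 1 member higher and 4 lower at an unadjusted p under 0.05. None of either list passed adjusted over the list alone, except Sox8 without young replicate 1 (0.0124). The myogenic median was negative with 1 array left out for aged replicate 1 (-0.10), young replicate 1 (-0.19) and young replicate 2 (-0.11), and with the covariate (-0.42). The counts of 1 higher and 4 lower were 0 and 0 without aged replicate 1, 4 and 3 without aged replicate 2, 2 and 4 without young replicate 1 and 3 and 0 without young replicate 2.

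Genes of mature muscle fibres shifted higher through 1 array, and endothelial genes shifted lower through 1 array. The myofibre list had 24 measured members, 23 of them positive, with a median of 1.02. The fast troponin gene Tnnt3 was read at 12.70 in aged replicate 1 but at 9.12 in aged replicate 2, against 8.58 and 7.92 in young cells, and Tpm2, encoding a tropomyosin, at 15.44 and 13.17 against 11.84 and 12.78. Only Tpm2 was higher and only Ryr1, the calcium release channel gene (-1.50 ± 0.35, SE), lower at an unadjusted p under 0.05, and 0 members passed adjusted over the list alone. The camera adjusted p was 9.57e-05, and adjusted p = 0.763 with an estimated correlation. Without aged replicate 1 the myofibre median was 0.01 (adjusted p of 0.773), without aged replicate 2 it was 2.12 with 20 members higher at an unadjusted p under 0.05 and 21 passing over the list alone, and with the exon against intron separation as a covariate it was -0.10. The endothelial list had 18 measured members and a median of -0.71, with none at an unadjusted p under 0.05; Cdh5, encoding VE-cadherin, was read at 9.99 and 6.83 in aged and 9.59 and 12.36 in young cells. Its camera adjusted p was 0.0284, and adjusted p = 0.763 with an estimated correlation. The endothelial median was 0.11 without young replicate 2 (adjusted p of 0.330), -0.36 without aged replicate 2 (adjusted p of 0.349) and -1.20 without young replicate 1, when 10 were at an unadjusted p under 0.05 and 7 passed adjusted over the list alone. With the covariate it was -1.60, and the call was lost after the filter on dim probe sets (adjusted p of 0.151) and without shared members (adjusted p of 0.0596).

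Imprinted genes that fall in expression as postnatal growth slows shifted lower in aged cells. Of 16 measured members 12 had negative differences, the median was -0.30, and 5 were at an unadjusted p under 0.05, among them Dlk1, a Notch-like ligand of growing muscle (-1.78 ± 0.41, SE), Mest (-1.64 ± 0.49), Peg10 (-1.28 ± 0.45) and the growth factor receptor adaptor gene Grb10 (-1.10 ± 0.30). None passed adjusted over the list alone. The camera adjusted p was 0.00477, and adjusted p = 0.530 with an estimated correlation. The median was -0.46 without young replicate 2 and -0.56 both after the dim filter and without shared members. The count of 5 was 2 without aged replicate 1, and over the list alone 3 passed without aged replicate 2 and 1 without young replicate 2, and with the exon against intron separation, lower in aged arrays, as a covariate the call was lost (median -0.31, adjusted p of 0.182). Without aged replicate 1 Mest differed by -0.97 and Peg10 by -0.72. Igf2 differed by -0.20 ± 0.45, a sign that turned without aged replicate 2 (0.35) and without young replicate 2 (0.03). The list of postnatal growth factors and receptors was not called (13 measured, median 0.00, mean -0.14, adjusted p of 0.570), and its median took either sign with 1 array left out, but Igf1, encoding insulin-like growth factor 1, was at 13.99 and 13.82 in aged and 15.15 and 15.46 in young cells. Its difference of -1.40 ± 0.30 (SE) was the 1 in that list to pass adjusted over the list alone (0.0483), and with any 1 array left out it did not (0.100 to 0.297).

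Genes of cell cycle inhibition and senescence shifted lower, not higher, in aged cells, by a small amount. Of 11 measured members 8 had negative differences, the median was -0.35, and 2 were at an unadjusted p under 0.05: the CDK inhibitor gene Cdkn1b (-1.17 ± 0.29, SE), and Igfbp3 (-1.95 ± 0.74), which encodes a secreted IGF-binding protein. Cdkn2a, a much used senescence marker, was read below the median of the intron controls in all 4 arrays, so its difference of 0.21 ± 0.31 says little about its expression. Cdkn1a differed by 0.13 ± 0.36, turning sign without aged replicate 2 (-0.18) and without young replicate 1 (-0.11). None passed adjusted over the list alone. The camera adjusted p was 0.0284, and adjusted p = 0.530 with an estimated correlation. The call was lost without aged replicate 1 (median -0.36, adjusted p of 0.151), without young replicate 2 (-0.33, adjusted p of 0.298) and with the exon against intron separation as a covariate (-0.44, adjusted p of 0.0705), and the median was -0.19 without aged replicate 2 and -0.53 without young replicate 1, when 1 member passed over the list alone. The median was -0.61 after the dim filter, the count of 2 was 1 without aged replicate 1, aged replicate 2 or young replicate 2, and Igfbp3 differed by -0.77 without young replicate 2. Secreted senescence factors were not called (25 measured, median 0.11, adjusted p of 0.189), and their median was 0.20 without aged replicate 2 and 0.24 without young replicate 1. In that list the stromelysin gene Mmp3 (-2.11 ± 0.32) passed adjusted over the list alone (0.0178), but not without aged replicate 1 (0.137), young replicate 1 (0.0560) or young replicate 2 (0.0676). The FGF inhibitor gene Spry1, known from quiescent satellite cells, differed by -0.08 ± 0.39 and was positive without aged replicate 2 (0.17), without young replicate 1 (0.29), after a second quantile normalization (0.017) and with the covariate (0.042).

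Cholesterol synthesis and proteasome genes shifted slightly lower in aged cells. The cholesterol list had 16 measured members, 13 of them negative, a median of -0.32 and 2 at an unadjusted p under 0.05, Idi1 (-1.24 ± 0.47, SE) and Hmgcs1 (-1.09 ± 0.43), which encode early enzymes of the pathway. The proteasome list had 20 measured members, 17 of them negative, a median of -0.26 and none at an unadjusted p under 0.05, with Psmd2 at -0.63 ± 0.30. None of either list passed adjusted over the list alone. Camera adjusted p-values were 0.0326 and 0.0358, and with an estimated correlation adjusted p = 0.691 and adjusted p = 0.763. The cholesterol median was -0.73 without young replicate 1. Lss, named after its value was seen, differed by 1.90 without young replicate 2, opposite to the list. The cholesterol call was lost without aged replicate 1 (median -0.34) and without young replicate 2 (median -0.07). It was also lost in camera after a second quantile normalization (adjusted p of 0.0791) and after the dim filter (adjusted p of 0.0878). The proteasome call was lost in those last 2 settings (0.101 and 0.151), without aged replicate 1 (median 0.05, adjusted p of 0.691), without young replicate 1 (-0.19, adjusted p of 0.249) and without young replicate 2 (-0.35, adjusted p of 0.0648), and the median was -0.59 without aged replicate 2. Without aged replicate 1 Idi1 differed by -0.62 and Hmgcs1 by -0.56. Members at an unadjusted p under 0.05 changed in number in both lists with single arrays left out. Without young replicate 2 those of the cholesterol list pointed both ways. With the exon against intron separation as a covariate the cholesterol median was -0.48 and the proteasome median was 0.17.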

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

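The tests of array quality, of macrophages, of granulocyte precursors, of dilution of muscle cells and of fewer fibroblasts, and the intervals between arrays, were chosen after the results they weigh were seen; those of other splits of the arrays were not.

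A signal lay in array entries that the gene comparison leaves out. Of 5222 control probe sets placed in introns, 245 (4.69%) were at least 1 log2 unit higher in aged arrays at an unadjusted p under 0.05 in limma and 65 were lower, with 0 past the adjusted threshold and a median of 0.23. Of 1324 exon control probe sets, 17 were higher and 77 lower by the same measure, with a median of -0.15.

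Immune cell markers were higher in aged arrays, with Elane, Mpo and Jchain among the largest differences. Array quality stays open: the mean shift of 52 pooled markers was 1.15, and 1.82 with the exon against intron separation as a covariate (camera adjusted p of 2.96e-16 at the preset correlation, adjusted p = 0.779 with an estimated correlation), but the 95% interval between arrays was -0.75 to 4.39. Macrophages that passed the sort stay open. Of 7 measured macrophage genes, all also in the macrophage list, 7 were positive, with a median of 0.51. The median in single pairs of an aged and a young array ran from -0.57 to 1.42, however. Of the 7 genes 5, C1qa among them (5.23 and 4.21 in aged arrays), were read below the median of the intron controls in all 4 arrays. These genes stayed near background in the aged arrays too, so their differences say little either way. Granulocyte precursors also stay open: 6 of 7 genes were positive with a median of 0.90 (0.76 to 1.34 over the pairs, against a bound of 1). Of the 7, 4 were below the median of the intron controls in all 4 arrays. The median gene, Fcnb, was among them, so the missed bound says little. The others were positive: Ms4a3 (3.93), Prtn3 (3.60) and Lcn2 (1.76). Ms4a3 and Prtn3 stood above that background in the aged arrays only, so picking them is not independent of their differences. Ms4a3 is also a gene named in the report, and Ltf and Mmp8 are also in the neutrophil list. The sort kept cells by CD29 and ITGA7, and with these values array quality, cells carried through the sort and an effect of age, which was not tested apart from them, cannot be told apart.

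Genes of the G2 and M phases were lower in aged arrays. With the exon against intron separation as a covariate the median went from -1.59 to -1.37 (camera adjusted p of 3.89e-09 at the preset correlation, adjusted p = 0.799 with an estimated correlation), no member passed over the list alone, and the 95% interval between arrays of the mean was -14.8 to 12.1. The G2/M median lay below that of satellite cell genes, by a difference of -1.49 (95% bootstrap interval over genes -2.06 to -0.94), but between arrays the difference in means was -1.38 with a 95% interval of -4.10 to 1.34. Array quality, dilution of muscle cells by other cells and an effect of age, which was not tested apart from them, cannot be told apart with 2 arrays per age.

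Collagen genes were lower in aged arrays. Their median went from -0.79 to -0.71 with the exon against intron separation as a covariate (camera adjusted p of 1.24e-05 at the preset correlation, adjusted p = 0.779 with an estimated correlation), and the 95% interval between arrays of the mean was -3.11 to 1.57. With all arrays the 12 fibroblast markers outside the matrix list, 7 of them negative, had a median of -0.25 (95% bootstrap interval over genes -0.78 to 0.33). Col1a1, Col1a2, Col3a1 and Col5a2 had a median of -2.37, also with all arrays. The markers' median was -0.70 without young replicate 1, near 0 without aged replicate 1 and 0.20 without young replicate 2. Between arrays the 95% interval of the markers' mean was -1.90 to 1.23. Tendon cell markers, of another collagen-rich cell type, were lower too (median -0.41, and -1.04 with the covariate; Kera -2.85, Tnmd -2.06). Array quality, fewer fibroblasts carried through the sort and an effect of age, which was not tested apart from them, cannot be told apart with 2 arrays per age.

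The 4 arrays can be split into 2 and 2 in 3 ways, which is too few for a share under 0.05. For differences of at least 1 log2 unit at an unadjusted p under 0.05, 1 split, that by age, gave as many as 1003, and the highest of the others gave 451. For called lists, 1 split, again that by age, gave as many as 19, and the highest of the others gave 9.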

How the results depend on the processing

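The exon against intron separation as a covariate and the lists without shared members were chosen after the results were seen.

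No gene passed after a second quantile normalization, median centring, the dim filter, a trended or robust prior, a required 1 log2 unit or with every entry of the table, and none passed with the covariate. In the replicate block 2 passed (Elane and Mpo, adjusted p of 0.0400 in limma) and 18 lists were called, with the NF-kB list lost (adjusted p of 0.0515); deviations of same-numbered arrays correlated at -0.05, so the numbers were not taken to pair the arrays. Of the differences of at least 1 log2 unit, 442 higher and 561 lower, median centring gave 403 and 600, a second quantile normalization 473 and 502, and the covariate 494 and 469. The dim filter left 838 probe sets at an unadjusted p under 0.05 against 1438, since fewer were tested. The G2/M, collagen, interferon, macrophage, class I and B cell lists kept their call in 13 of 15 alternatives each, all but the estimated correlation and fry. With an estimated correlation 0 lists were called, with an adjusted p of 0.530 for the G2/M, interferon, collagen and macrophage lists. By fry 0 were called, with an adjusted p of 0.351 for G2/M, interferon and macrophages and 0.241 for collagens. Both tests allow for correlation between genes. The estimated correlation was 0.46 for G2/M, 0.095 for interferon and 0.062 for macrophage genes. For collagens it was -0.033, below the preset 0.01, so a higher correlation did not remove that call in camera. The cause was not tested further.

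With the covariate the myofibre (adjusted p of 0.477) and proteasome (0.162) lists lost their call and turned direction, satellite cell genes turned (0.338), and so did Itga7 (0.33) and Spry1 (0.042). Spry1 also turned after a second quantile normalization (0.017). The cause was not tested.

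With 1 array left out in turn, which leaves 1 array in an arm that is assumed to vary like the others, genes passing ran from 0 to 1, differences of at least 1 log2 unit at an unadjusted p under 0.05 from 1036 to 1994, and called lists from 12 to 21. Adjusted p ran from 1.74e-20 to 0.773 for myofibre, 2.67e-05 to 0.691 for proteasome, 2.90e-12 to 0.349 for endothelial, 0.00997 to 0.677 for satellite cell and 0.410 to 0.969 for myogenic commitment genes. Differences ran from -0.41 to 0.64 for Pax7, -0.39 to 0.10 for Itga7, -0.18 to 0.44 for Cdkn1a, -0.46 to 0.29 for Spry1 and -0.76 to 0.35 for Igf2. The number of arrays, and the separation of signal from background (0.792 to 0.849), limit the precision.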

Other observations

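The exon against intron separation as a covariate was chosen after the results were seen, and the other tests of this part were not.

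Genes of matrix remodelling enzymes moved in both directions and were not called as a list (23 measured, median 0.05, mean -0.16, camera adjusted p of 0.508). At an unadjusted p under 0.05, 3 were higher and 5 lower; none passed in limma over all genes, and 3 passed adjusted over the list alone: the metalloprotease gene Adam12 (-2.34 ± 0.31, SE), Mmp3 (-2.11 ± 0.32) and Mmp11 (1.49 ± 0.31). The counts of 3 higher and 5 lower were 2 and 3 without aged replicate 1 and also without young replicate 1. The count of 3 passing over the list alone was 0 without aged replicate 1, 2 without aged replicate 2, 2 without young replicate 1, and 0 with the exon against intron separation as a covariate, and the list median was negative without aged replicate 2 (-0.18) and without young replicate 2 (-0.14). Among circadian clock genes (17 measured, median 0.20, adjusted p of 0.106), Hlf, a transcription factor of clock output, differed by 1.52 ± 0.30 and passed adjusted over the list alone (0.0436), but not with any 1 array left out (0.0998 to 0.233); the list was called higher without young replicate 1 (median 0.31, adjusted p of 0.0203), but its median was 0.11 without aged replicate 2 (0.283) and 0.09 without young replicate 2 (0.613). TGF-beta and BMP genes (22 measured, median 0.32, adjusted p of 0.0936) were called higher without aged replicate 1 (0.0441), without young replicate 1 (0.00749) and with the covariate (0.00714), but their median was 0.17 without aged replicate 2 (0.450) and 0.07 without young replicate 2 (0.721). Histone and chromatin genes (23 measured, median -0.25, adjusted p of 0.0834) were called lower without young replicate 1 (0.0165), but had an adjusted p of 0.375 without aged replicate 1 (median -0.14) and of 0.582 without young replicate 2.

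Wnt genes were not called (24 measured, median 0.06, mean -0.01, adjusted p of 0.878), with 2 members higher and 2 lower at an unadjusted p under 0.05, among them the ligand gene Wnt4 (1.61 ± 0.35, SE) and the Wnt inhibitor gene Dkk2 (-1.48 ± 0.33). FGF and MAPK feedback genes were not called (20 measured, median -0.08, adjusted p of 0.924), with the ERK phosphatase gene Dusp6 at -1.44 ± 0.41 and Dusp5 at 1.06 ± 0.34. Glycolysis genes were not called (17 measured, median 0.18, adjusted p of 0.508), with the phosphofructokinase gene Pfkp at 1.17 ± 0.32 and the pyruvate dehydrogenase kinase gene Pdk1 at -1.40 ± 0.39. Immediate early and dissociation genes were not called (24 measured, median 0.08, adjusted p of 0.268), with the AP-1 gene Fosl1 at 1.45 ± 0.29. The Wnt counts of 2 and 2 were 1 and 1 without aged replicate 2 and 1 and 2 without young replicate 1. The Wnt median was -0.07 without aged replicate 1. The FGF median was negative while its test pointed higher, and it was positive without aged replicate 1 (0.0070), young replicate 1 (0.11) or young replicate 2 (0.06). The glycolysis median was 0.38 without aged replicate 2, and that of immediate early genes was 0.16 without aged replicate 2 and 0.018 without young replicate 2. None of these members passed adjusted over the list alone, and 1 Wnt gene did without young replicate 1.

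The other lists that were not called had these medians and camera adjusted p: heat shock proteins 0.23 and 0.196, p53 targets -0.32 and 0.204, lipid uptake and oxidation -0.16 and 0.204, ribosomal proteins -0.12 and 0.234, oxidative phosphorylation -0.14 and 0.242. Erythroid cells and platelets had 0.34 and 0.336, pericytes and smooth muscle 0.22 and 0.336, antioxidant genes 0.03 and 0.425, ribosome biogenesis -0.10 and 0.589. Adipocytes had 0.05 and 0.682, autophagy and lysosome -0.12 and 0.798, Schwann cells and nerve -0.16 and 0.799, Notch 0.10 and 0.917 and the unfolded protein response -0.03 and 0.924. With 1 array left out, heat shock proteins were called higher without aged replicate 1 (0.0425) and without young replicate 1 (0.0163), as they were with the covariate (0.00230), and their median was -0.04 without young replicate 2. Pericyte and smooth muscle genes were called higher without young replicate 1 (median 0.58, adjusted p of 0.000107), and their median was -0.06 without aged replicate 1 and -0.25 without young replicate 2. Without aged replicate 2, ribosomal proteins (0.00624), oxidative phosphorylation (0.0164) and ribosome biogenesis (0.0257) were called lower, and without aged replicate 1 their medians were 0.06, 0.03 and 0.17. The other lists of this paragraph were not called with any 1 array left out or with the covariate, although the median changed sign with 1 array left out for the antioxidant, adipocyte, Schwann cell, Notch and unfolded protein response lists. The erythroid and platelet median was 0.03 without aged replicate 1, 0.68 without aged replicate 2 and 0.08 without young replicate 1. The medians also moved for p53 targets (-0.17 without young replicate 2), lipid genes (-0.27 without aged replicate 2) and autophagy genes (-0.011 without young replicate 1). The median and the test or the mean pointed apart for adipocytes, autophagy, Notch and the unfolded protein response.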
